A study of Homo sapiens with 2 samples.

How the data were processed

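RNA from 1 neo control sample and 1 shATMIN sample of SAS cells was measured on 1-colour arrays with Cy5 dye. Per the labels' protocols, hairpin plasmids were delivered with a lipid reagent, cells were moved after 24 h to medium with 10% serum and 3 µg/mL puromycin, and resistant clones were grown. The same text is given for the neo control, whose construct and selection are not given in the sources used here. RNA was extracted with Trizol and amplified before labelling, per the labels. The labels list 2 arrays per sample, and 1 value per probe and sample was deposited. The scanner, the background correction, the way the arrays were combined and any normalization are not given in the sources used here.

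The deposited values are linear intensities of each probe after background subtraction, as read from the values themselves. They ran from -1.002 to 65510 in the neo control and from -2.00 to 65511 in the shATMIN sample. In the neo control 46 probes were below 0 and 28 at exactly 0, and in the shATMIN sample 41 and 32. Above 60000, near the top of the scanner range, lay 77 and 57 probes. The quartiles of the samples differed, and no scaling of one sample to the other was visible. The number of unassigned columns was 0.

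Probe names came from the platform annotation, which was updated through a RefSeq gene table of assembly GRCh38.p14. Of 31741 probes, 24740 named 1 gene, 977 several and 6024 none. Of the probes with 1 gene, 22722 had a current symbol, 1948 were updated and 70 kept their older name. No positions are given, because the build behind the array is not given in the sources used here.

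Values below 0 were set to 0 and transformed as log2(intensity + 1). This scale understates the differences of dim genes. Each gene was represented by the probe with the highest mean among probes that name exactly 1 gene. A gene was compared where that mean reached the 40th percentile of all probes, a log2 level of 5.90. The difference was always shATMIN minus neo control. With 1 sample per group no test was made, and genes were counted by a rule of size of 2-fold. Probes of the same gene disagreed with an SD of 0.34 over 2973 genes with several compared probes, and 62.8% of those genes had probes of one sign. That SD was the tolerance for single genes across settings.

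Named genes were chosen by a rule written before the data were examined. It took ATMIN and DYNLL1, the 12 highest and 12 lowest genes whose compared probes had one sign, leaving out uncharacterised symbols, olfactory receptors and Y-linked genes, and up to 4 members with the greatest absolute difference in each list. Examples named beyond that rule (CALR, DUSP6, VIM, NOTCH3, TFRC, the genes at the top of the scale and second probes) were chosen after their values were seen. The 34 gene lists were also fixed before, and 33 had at least 5 compared members. The median of a list was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a list was set apart outside the central 95%. The percentile describes these libraries.

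Low intensities lie near multiples of 0.5, as the mean of 2 whole-number readings with slightly unequal scale factors would. The fitted factors were 1.0022 and 0.9978 in the neo control and 1.0019 and 0.9981 in the shATMIN sample. The pairs were recovered from the small departures from those multiples, for intensities under 1000. There 99.7% of values in each group were resolved within a tolerance of 5e-05. A wrong step for these departures resolved 12.6% and 12.5% of values under 100, where the right step resolved 100%. The wrong step was tried on fewer candidate multiples than the right one, so these shares may overstate the contrast. The contrast was not measured above 100.

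The calculation was tested on simulated data with the real levels and a noise SD of 0.3. Of 200 genes given a difference of 1.5, 93.5% were recovered among 12421 genes. Of the others, 11 passed the rule, and 4.5% of 200 unshifted lists were set apart. That noise was below the SD of 0.34 between probes and of 0.38 over compared genes. The 11 therefore do not estimate how many genes passed the rule by noise in the real data. Alternatives covered normalization, the dim filter, several probes per gene, probe naming, the pseudocount, the size rule and the matching. A further 4, scaling to the 75th percentile, removal of trends on level and gene span, leaving out probes over 60000, and genes whose probes have one sign, were added after seeing the data. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6 (loess, span 0.3) and matplotlib 3.10.9.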

Results

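Gene expression was measured in SAS cells, an established line of human tongue squamous cell carcinoma, of 2 kinds, a control that the labels call neo and cells with a short hairpin RNA against ATMIN (shATMIN). ATMIN encodes the ATM interactor, a zinc finger protein of the DNA damage response that also acts as a transcription factor, and the stated question was whether its knock-down affects cancer progression. There was 1 sample per group, so the differences have no replicate check and no p-value is given. The labels describe puromycin selection and hairpin plasmids for both samples alike, and what the neo control carried and how it was selected are not given in the sources used here, which bears on every difference. Each sample had 1 intensity for each of 31741 probes, and the labels list 2 arrays per sample. The median intensity was 109 in the neo control and 106 in the shATMIN sample, and the upper quartile was 629 against 535. The number of arrays limits the precision of every value below.

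ATMIN, the targeted gene, had an intensity of 105 in the neo control and 61.5 in the shATMIN sample, a difference of -0.76 on the log2 scale. That is 1.70-fold, short of the 2-fold rule, and 61.5 lay just above 58.9, the level required for comparison. As deposited, 166 of 12421 compared genes were at least 2-fold lower and thus lower by more than ATMIN. At the looser cut of 1.5-fold 1517 were lower. The size of the ATMIN difference therefore does not set it apart. Its other probe read 51.5 and 26.5, a difference of -0.93, and lay below the level required for comparison. After removal of the trend on level the ATMIN difference was -0.75, and 50 genes were then at least 2-fold lower. Under scaling of the samples to their 75th percentile the ATMIN difference was -0.53. DYNLL1, which encodes a dynein light chain and is the best known transcriptional target of ATMIN, read 13533 in the neo control and 13793 in the shATMIN sample, a difference of 0.03 as deposited, 0.21 after removal of the trend on level and 0.26 with scaling to the 75th percentile.

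Among 12421 compared genes, the lowest in the shATMIN sample included IL11, a cytokine of the interleukin 6 family, at 117 against 696 in the neo control. CCND2, which encodes the cell cycle regulator cyclin D2, read 5312 against 16449, a difference of -1.63. HMGA2, an architectural chromatin protein of embryonic and tumour cells, read 817 against 2667. The highest included SPP1, which encodes the secreted phosphoprotein osteopontin, at 541 against 76.5, and FN1, which encodes the matrix protein fibronectin, at 4284 against 1228. KLK10, a secreted serine protease of the kallikrein family, read 8677 against 2625.

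The remaining genes of the lowest 12 were CD248 at -3.74, ZFYVE1 at -1.73, RASSF8 at -1.61, SEMA3B at -1.61, RDH11 at -1.54, RELN at -1.53, PXDN at -1.52, PLCB3 at -1.47 and DNMT3A at -1.40. IL11 stood at -2.56 and HMGA2 at -1.70. RASSF8 was low on both of its compared probes, at -1.61 and -1.35. A second HMGA2 probe gave -0.08 and a second DNMT3A probe gave -0.16, so those differences rest on 1 probe each. In the shATMIN sample CD248, PLCB3 (36.0) and DNMT3A (58.0) read below 58.9, the level that the mean of a compared gene had to reach, so the size of their differences and their place among the lowest are uncertain. CD248 rests on a single reading: the pair of values recovered behind the neo control value was 17.0 and 476, and that of the shATMIN sample was 17.03 and 17.97.

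The remaining genes of the highest 12 were ANKRD36BP1 at 3.08, NLRP7 at 2.40, the linker histone gene H1-1 at 2.07, TAF13 at 2.06, ZNF800 at 1.81, RBMS3 at 1.78, the small nuclear RNA gene RN7SK at 1.75, KANK4 at 1.74 and PTDSS1. SPP1 stood at 2.81, FN1 at 1.80 and KLK10 at 1.72. PTDSS1, a phosphatidylserine synthase, was listed at 0 in the neo control and at 8791 in the shATMIN sample, and no fold is given. Whether that 0 is an absent transcript or an unread spot is not given in the sources used here, so its place among the highest genes is open. In the neo control ANKRD36BP1 (44.5), NLRP7 (36.5), KANK4 (32.0) and RBMS3 (51.4) read below 58.9, and the size and rank of their differences are uncertain. The other compared probes of ZNF800 gave 2.75 and 0.03. For RBMS3 the pair behind the neo control value was 8.02 and 94.8 and a second compared probe gave 0.12, and a second FN1 probe was listed at 0 in both samples.

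By the rule of size, 57 of the 12421 genes were at least 2-fold higher in the shATMIN sample and 166 were at least 2-fold lower, so that 74.4% of these genes were lower. The median over compared genes was -0.16 and 70.7% of them were lower, and single differences are best read against that shift. After a trend of the difference on mean level was removed, 95 genes were higher and 50 lower, so that 34.5% were lower. With each sample scaled to its 75th percentile the split was 122 higher and 36 lower. The direction of the imbalance thus differed with the scaling.

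**Figure D1:**
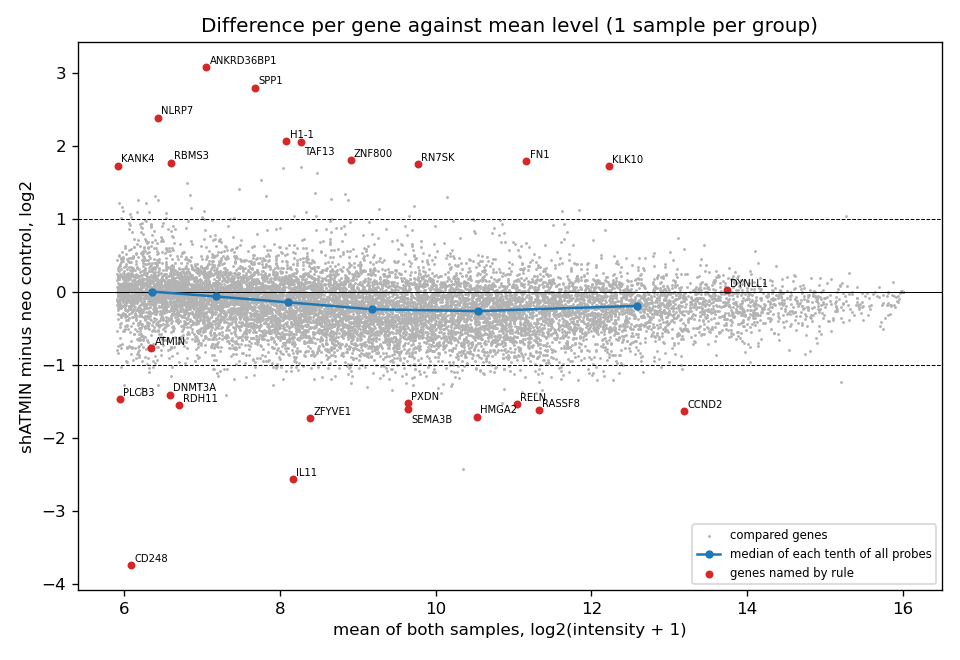
Each grey point is a compared gene, with the mean log2 intensity of both samples on the horizontal axis and the shATMIN minus neo control difference (log2) on the vertical axis. The blue line joins medians of probe groups of equal size by level, from 0.01 down to -0.26 and back to -0.19 at the brightest. Dashed lines mark 2-fold. PTDSS1, listed at 0 in the neo control, lies outside the plotted range.

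Genes of cholesterol and fatty acid synthesis were lower in the shATMIN sample as a group: 22 of 22 compared members were lower, with a median of -0.56 against -0.21 in random lists matched on level. The sterol demethylase CYP51A1 stood at -1.18, the squalene epoxidase SQLE at -1.03, and the sterol oxidase MSMO1 at -0.92, with -0.19 on a second MSMO1 probe. The stearoyl-CoA desaturase SCD read 3845 in the shATMIN sample against 7690 in the neo control. The list lay at percentile 0.01 of 10000 matched random lists, which describes these libraries and is not a p-value. After scaling to the 75th percentile, quantile normalization or removal of the trend on level, 18 of the 22 were lower and the percentile was at most 0.01. Scaling adds one constant to every gene, so it cannot change the percentile.

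Feedback and immediate early genes of MAPK signalling were also low, with 18 of 23 compared members lower, a median of -0.38 against -0.14 in matched lists and a percentile of 0.24. The transcription factor genes ETV4 and ETV5 stood at -1.09 and -1.03, and SPRED2 and DUSP5, which encode inhibitors of the pathway, at -0.97 and -0.80. DUSP6, a phosphatase that acts on ERK, was higher at 0.50. A second ETV5 probe gave 0.18. With each sample scaled to its 75th percentile 15 of the 23 members were lower.

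**Figure D2:**
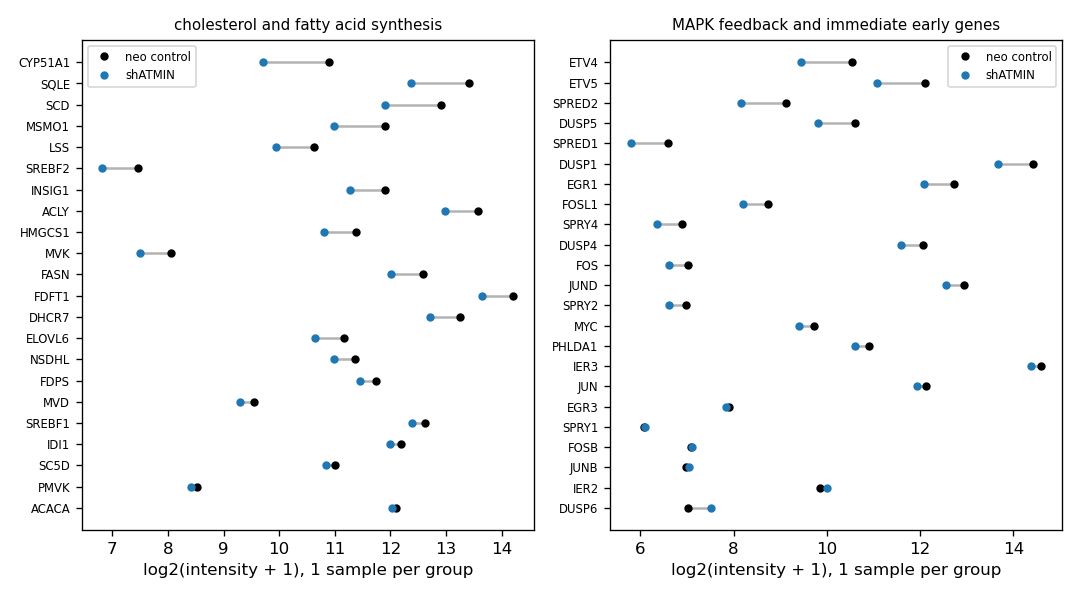
Log2 intensity of each compared gene in the neo control (black) and in the shATMIN sample (blue), for cholesterol and fatty acid synthesis on the left and MAPK feedback and immediate early genes on the right. All 22 genes on the left and 18 of 23 on the right were lower in the shATMIN sample in the values as deposited.

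Of the growth factor receptors and ligands, 17 of 22 were lower, with a median of -0.38 and a percentile of 1.92. FGF2 stood at -1.09, the insulin-like growth factor receptor gene IGF1R at -0.87 on 1 probe and -0.03 on another, the EGF family ligand gene EREG at -0.85 and the ephrin receptor gene EPHA2 at -0.72. Genes of the unfolded protein response had 17 of 20 members lower, with a median of -0.38 and a percentile of 2.23. TRIB3 stood at -1.01, DNAJC3 at -0.87, HYOU1 at -0.80 and EDEM1 at -0.76, while the chaperone gene CALR was higher at 0.68 and a second DNAJC3 probe gave 0.54. Both lists lay inside the central 95% of matched lists after the trend on level was removed, at percentiles 2.51 and 3.87, with 13 of 22 and 14 of 20 members lower. Over the alternatives their percentiles reached 40.7, with the mean of each gene's probes, and 11.7.

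A further 7 lists lay above the central 95% of their matched lists because their medians were close to 0 where matched genes were lower. Keratinocyte differentiation had 8 of 11 members higher and a median of 0.09, with S100A9 at 0.64 and S100A8 at 0.63. The cornified envelope gene LOR stood at 1.03, but the pair behind its neo control value was 2.00 and 90.8 and overlapped that of the shATMIN sample, 83.8 and 108.2. Mesenchymal genes had 8 of 15 higher and a median of 0.03, with FN1 and SNAI2 at 1.80 and 0.80 and with ACTA2 and VIM at -0.56 and -0.49. HLA and antigen presentation had 7 of 13 higher and a median of 0.03, with HLA-C at 0.37, PSMB9 at 0.35 and TAP2 at -0.78. The percentiles of these lists were 98.4, 97.9 and 98.8. The keratinocyte list lay inside the central 95% without a dim filter, at percentile 80.2, and after removal of the trends on level and gene span, at 95.5, as did the HLA list after the latter, at 95.9. The mesenchymal list lay inside the central 95% after removal of the level trend, at percentile 84.8, and after quantile normalization, at 85.6.

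Among NF-kappaB targets and inflammatory cytokines 10 of 20 were higher, the median was -0.003 and the percentile 98.3, with PTGS2 at 0.87 and IL11 at -2.56. IL6 stood at 0.71, of uncertain size because its neo control value of 55.5 lay below 58.9. Cytoplasmic dynein and dynactin had 11 of 17 lower, a median of -0.03 and a percentile of 98.4, with DYNC1I2 at 0.47 and PAFAH1B1 at -0.64. Oxidative phosphorylation had 15 of 21 lower, a median of -0.03 and a percentile of 98.6, with cytochrome c, CYCS, at -1.08 and NDUFV1 at -0.55. Cytosolic ribosomal protein genes had a median of -0.02 over 20 genes and a percentile of 99.0, with RPL37 at 0.36. However, 9 of those 20 genes were over 60000, and RPL8, RPL11, RPLP1, RPS23 and RPS27 were at the top of the scale in both samples, so their differences near 0 cannot be read. The list lay inside the central 95% without such probes, at percentile 83.9, after removal of the level trend, at 95.8, and after quantile normalization, at 87.7. After removal of the level trend 14 of 17 dynein and dynactin genes, 13 of 20 NF-kappaB genes and 13 of 21 oxidative phosphorylation genes were higher. Scaling to the 75th percentile adds one constant to every gene and by construction took the medians of the NF-kappaB, dynein and oxidative phosphorylation lists above 0, to 0.23, 0.20 and 0.21. These 3 lists also lay inside the central 95% under at least 1 alternative, at percentiles down to 90.9, 96.7 and 92.2.

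**Figure D3:**
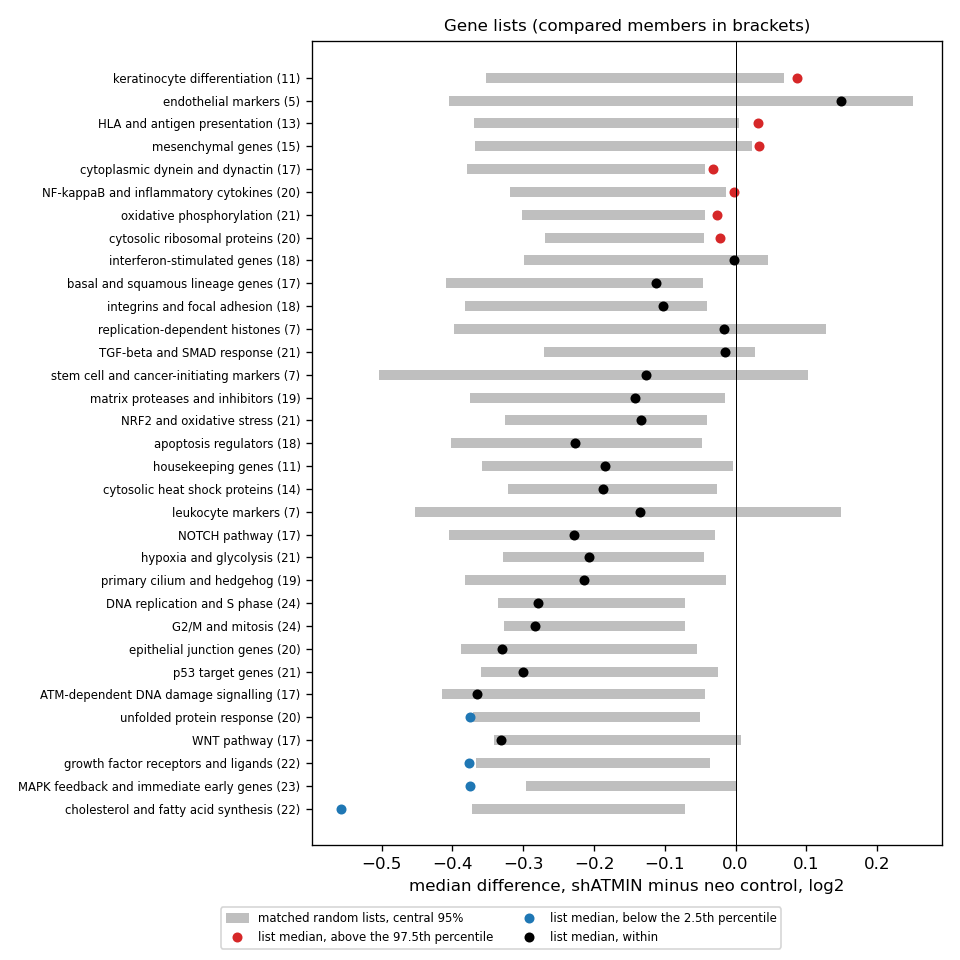
Median shATMIN minus neo control difference (log2) of each gene list, as points, against the central 95% of 10000 random lists matched on level, as grey bars, with compared members in brackets. Of 33 lists, 4 lay below their bar (blue) and 7 above it (red), where 1.65 would fall outside if lists were random draws of genes. Members of a list may vary together, which that figure leaves out.

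The remaining lists lay inside the central 95% of their matched lists. Their counts of higher and lower members are those of the values as deposited: they carry the shift of -0.16 over all compared genes, and after removal of the level trend the median of 14 of all 33 lists had the other sign. ATM-dependent DNA damage signalling, the pathway of the ATM kinase, had 16 of 17 members lower, with TRIM28 at -0.87, PRKDC at -0.85 and WRNIP1 at -0.72, and a percentile of 6.36. The p53 target genes had 19 of 21 lower, with RRM2B at -1.03, and a percentile of 8.27. MDM2 stood at -0.99 on 1 probe and 0.42 on another. Genes of DNA replication and S phase had 23 of 24 lower at percentile 12.3, with POLA1 at -0.92, and those of G2/M and mitosis had 22 of 24 lower at percentile 9.77, with CENPE at -0.75. After removal of the level trend 15 of 24 replication genes, 16 of 24 mitosis genes, 14 of 21 p53 targets and 12 of 17 ATM-dependent genes were lower. PCNA, counted as lower among the replication genes, ENO1 among the glycolysis genes and ATP5F1B among the oxidative phosphorylation genes were at the top of the scale in both samples, as was H4C3, counted as higher among the histones, and their directions cannot be read. The WNT pathway had 13 of 17 lower at percentile 3.08, with TCF7L2 at -0.84 and LEF1 at -0.77. A second LEF1 probe gave -0.35. Epithelial junction genes had 16 of 20 lower at percentile 8.66, with the tight junction gene TJP1 at -0.82 and DSC2 at -0.74.

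Basal and squamous lineage genes had 9 of 17 lower at percentile 88.0, with KRT6A at 1.00, KRT14 at 0.99 and TP63 at -1.19 on 1 probe and -0.06 on another. Integrins and focal adhesion genes had 10 of 18 lower at percentile 88.8, with ITGB8 at 0.99 and PXN at -0.95. Matrix proteases and their inhibitors had 15 of 19 lower at percentile 67.5, with MMP3 at -1.24 and TIMP2 at -1.03. Among interferon-stimulated genes 9 of 18 were higher at percentile 91.4, with OASL at 1.36. IFI44 stood at 1.32, of uncertain size because its neo control value of 52.0 lay below 58.9. TGF-beta and SMAD response genes had 11 of 21 lower at percentile 90.3, with ID2 at 0.73 and TGFBR2 at -0.86 on 1 probe, where another read 601 and 602. Other compared ID2 probes gave 0.48 and 0.28. The NOTCH pathway had 13 of 17 lower at percentile 42.2, with NOTCH1 at -1.14 and NOTCH3 at 0.50.

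Genes of the primary cilium and hedgehog signalling had 13 of 19 lower at percentile 39.1, where KIF3A was at -1.06 on 1 probe and 1.25 on another. Apoptosis regulators had 13 of 18 lower at percentile 45.6, with MCL1 at -0.78. Genes of NRF2 and oxidative stress had 16 of 21 lower at percentile 72.7, with SLC7A11 at -0.81. Hypoxia and glycolysis had 18 of 21 lower at percentile 35.2, with PFKL at -0.86 on 1 probe and -0.38 on another. Cytosolic heat shock proteins had 9 of 14 lower at percentile 39.6, with HSP90AA1 at 1.05 on 1 probe and -0.12 on another. Stem cell and cancer-initiating markers had 5 of 7 lower at percentile 62.6, with PROM1 at 0.74, and replication-dependent histones had 4 of 7 lower at percentile 76.8, with H1-4 at 0.58. Without probes over 60000 the histone list lay at percentile 41.3, with a median of -0.14. Housekeeping genes had 10 of 11 lower at percentile 44.5, with PGK1 at -0.46 and TFRC at 0.20, and after removal of the level trend 6 of 11 were lower. Scaling to the 75th percentile, which adds one constant to every gene, by construction took their median from -0.18 to 0.05.

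Markers of other cell types showed no list apart from its matched lists. Leukocyte markers had 6 of 7 compared members lower at percentile 43.2, with CD68 at -0.64. Endothelial markers had 3 of 5 higher at percentile 92.6, with CDH5 at -0.60. Of 12 fibroblast markers 4 were compared, too few for a percentile, and among them COL1A1 stood at -0.12 and MMP2 at 0.11.

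As a measure of technical spread, the pair of values behind each deposited value was recovered for 7418 genes of low and medium intensity, a step chosen after seeing the data. Whether the pair is the 2 arrays listed per sample is not given in the sources used here. Their SD around the sample value was 0.17 in each group on the log2 scale, and 35 genes of the neo control and 21 of the shATMIN sample differed at least 2-fold within the pair of the same sample. Between the groups 111 of these genes differed at least 2-fold. Dim genes showed no such excess: with both intensities under 100, 8 of 1251 differed at least 2-fold between the groups and 12 within each sample's pairs. With the higher intensity from 100 to 300, 45 differed between the groups, against 19 within neo control pairs and 9 within shATMIN pairs. From 300 to 1000 the counts were 58, 4 and 0. In each group the SD was 0.20 under 100 and 0.10 from 300 to 1000. This spread is technical and does not cover separate cultures or clones.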

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

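The tests of the level trend on the cholesterol list, of scaling, of gene span alone, and of members over 60000 by list were chosen after the results were seen. Probes without a gene name were not part of the comparison. Among 2672 of them above the dim filter, 19 were at least 2-fold higher in the shATMIN sample and 34 at least 2-fold lower. That was 1.98% of these probes against 1.80% of named genes. The units differ, since each named gene was counted once, by its brightest probe. The highest were PH_hs_0030581 at 3.61, whose neo control value of 24.5 lay below 58.9 and leaves its size and rank uncertain, and PH_hs_0046934 at 2.08. The lowest were PH_hs_0046468 at -4.39, with 3166 in the neo control and 150 in the shATMIN sample, and PH_hs_0030345 at -1.74. No explanation was tested for these probes.

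Cholesterol and fatty acid synthesis genes were lower in the shATMIN sample. A trend of the difference on mean level was tested as a cause, and after its removal the percentile of the list was 0. The matched lists already share the levels of the list, so that percentile could hardly change and adds no separate evidence. Against genes of the same level the list stood at -0.56 where matched lists stood at -0.21. Removal of the trend took the median to -0.34, with 18 of 22 members lower. Gene span, tested after removal of trends on level and span, also left a percentile of 0. The hairpin, the choice of clone and the arrays differ together between the samples, and no test here separates them. An effect of ATMIN on this group stays a hypothesis.

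The 7 lists above their matched lists were weighed against gene span and saturated spots. Removing the trends on level and span together left 1 of the 7 above, which met the outcome predicted for gene span, but the level trend alone had left 5 and the span step removed a median of 17.6% of the excess it left, a measure added after that count was seen. Removing the trend on gene span alone left 3 of the 7 above: the excess went from 0.21 to 0.14 for keratinocyte differentiation, from 0.16 to 0.12 for NF-kappaB and from 0.19 to 0.22 for mesenchymal genes, so a part played by gene span stays open. Leaving out probes over 60000 left 6 of the 7 above, which decides little, since 5 of the lists hold no such probe. That absence rules out saturated members for those 5, while the ribosomal list, with 9 of 20 members over 60000, went to percentile 83.9 and its place may come from saturation.

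More genes were lower than higher in the deposited values, and the absence of scaling between the samples was weighed as the cause. After removal of the trend on level 34.5% of genes past 2-fold were lower, against 74.4% before. The shift was 0.12 in the dimmest 10% of probes, -0.26 in the 10% next to the brightest and -0.19 in the brightest. It was thus not steady with level, and a single factor between the samples does not describe it. A technical trend with intensity and a real lowering of abundant transcripts cannot be told apart with 1 sample per group, since removing the trend centres the values by construction.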

How the results depend on the processing

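Scaling to the 75th percentile, the joint removal of trends on level and gene span, leaving out probes over 60000 and restricting to genes with probes of one sign were chosen after seeing the data. Only the cholesterol and MAPK lists were set apart under all 13 alternatives run on lists, at percentiles of 0 to 0.01 and 0.16 to 1.02. Some of these could not change the result. Centring on the median and scaling to the 75th percentile add one constant to every gene and leave every percentile as it was. Neither list holds a member over 60000, so leaving such probes out tests little for them. The cause of the differences below was not tested.

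The count of genes at least 2-fold higher was 57, and it was 96 after quantile normalization, 95 after removal of the level trend, 94 after removal of the trends on level and span, 122 after scaling to the 75th percentile, 154 without a dim filter and 29 with a filter at the 60th percentile. The count of genes at least 2-fold lower was 166, and it was 47, 50, 42 and 36 under the first 4 of these. The level trend left 57 of the 57 higher genes and 50 of the 166 lower ones past 2-fold. A rule of 1.5-fold gave 236 higher and 1517 lower, and a rule of 3-fold 15 and 8. The median over compared genes was -0.13 after centring on the median of all probes, 0.002 after quantile normalization and 0.07 after scaling to the 75th percentile. The ATMIN difference ranged from -0.76 to -0.53.

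List medians that lost their place outside the matched lists were as follows. After quantile normalization they were 0.16 for dynein, 0.0557 for ribosomal proteins, 0.0878 for mesenchymal genes, -0.17 for growth factor genes and -0.15 for the unfolded protein response. After removal of the level trend they were 0.0952 for ribosomal proteins, 0.0837 for mesenchymal genes, -0.18 for growth factor genes and -0.15 for the unfolded protein response. After removal of both trends they were 0.17 for HLA, 0.14 for NF-kappaB, 0.16 for dynein, 0.0562 for ribosomal proteins, 0.16 for keratinocyte differentiation, 0.12 for mesenchymal genes, -0.16 for growth factor genes and -0.13 for the unfolded protein response. Without a dim filter they were -0.0443 for ribosomal proteins, -0.19 for growth factor genes, 0.0327 for keratinocyte differentiation (percentile 80.2) and 0.0338 for mesenchymal genes.

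With a filter at the 60th percentile they were -0.0856 for NF-kappaB, -0.0582 for dynein, -0.12 for mesenchymal genes and -0.33 for the unfolded protein response. With the mean of a gene's probes they were -0.0701 for ribosomal proteins, -0.20 for growth factor genes (percentile 40.7), -0.0848 for oxidative phosphorylation and -0.29 for the unfolded protein response. Without probes over 60000 the ribosomal median was -0.11. Among genes whose probes have one sign it was -0.0425 for mesenchymal genes and -0.33 for the unfolded protein response. For that last list it was also -0.36 with the first gene of probes naming several and -0.38 with 5 bins of level.

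Other lists were set apart only under an alternative. TGF-beta genes reached 0.15 after quantile normalization, 0.16 without the level trend and 0.22 without both trends. The WNT pathway reached -0.19 after quantile normalization, -0.18 without the level trend, -0.18 without both trends, -0.42 with the filter at the 60th percentile and -0.34 with the mean of probes. Basal and squamous genes stood at 0.0313 both without a dim filter and with the mean of probes, and interferon-stimulated genes at 0.0904 without a dim filter.

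KIF3A turned from -1.06 to 0.0921 with the mean of its probes. Under that setting 15 other named genes differed by more than the tolerance, and with a pseudocount of 16, 5 did. No other alternative took a named gene past the tolerance of 0.34, but several could hardly have done so. Centring and scaling add the same constant, smaller than the tolerance, to every gene. The shift with level that trend removal takes out reached -0.26 in groups of probes by level, also short of it. A changed dim filter and the restriction to genes whose probes agree in sign only add or drop genes. Those settings therefore say little about how stable single genes are. No paired analysis was possible because each group has 1 sample. No sample can be left out for the same reason. Signal near background limits dim genes: the filter at the 60th percentile left values for 119 of the named genes.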

Other observations

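The family scan, the microRNA target lists and the let-7 hypothesis were chosen after seeing the data. Grouped by the leading letters of their symbols, 152 families had at least 10 compared genes. Of these 8 lay below and 9 above the central 95% of matched lists, where 3.8 would lie on each side if families were random draws of genes. Of these 17 families 7 lay inside after removal of the trends on level and gene span, the keratins among them at percentile 95.2. Counts are of the values as deposited and shift with the scaling. Translation initiation factor genes (EIF) had 45 of 51 lower, with a median of -0.30, and 35 of 51 lower after removal of the level trend. Vacuolar sorting genes (VPS) had 26 of 31 lower, with a median of -0.37, and 20 of 31 after that removal. Of the MAPK genes 11 of 13 were lower, with a median of -0.45, and 10 of 13 after it. Of the NDUFB genes of respiratory complex I, 7 of 11 were higher, with a median of 0.07, and of the keratins (KRT), 16 of 27 were higher, with a median of 0.03. Olfactory receptor genes (OR) had 67 of 117 higher, with a median of 0.04, and 82 of 117 after removal of the level trend. Their percentile was 100, and 99.99 after removal of both trends. Keratin-associated protein genes (KRTAP) had 16 of 25 higher, with a median of 0.09 at percentile 99.7, and 61.9 after removal of both trends. Long non-coding RNA genes (LINC) had 25 of 46 higher, with a median of 0.04 at percentile 98.5. The place of the keratins above their matched lists was thus shared with families of other kinds. Zinc finger genes (ZNF) had 172 of 279 lower, with a median of -0.08 at percentile 98.8 of their matched lists, and this direction flipped to 168 higher after removal of the level trend and, by construction of a constant added to every gene, to 199 higher after scaling to the 75th percentile. The medians of the other families named here kept their sign under each of the 4 scalings run.

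The low values of HMGA2 at -1.70, XPO4 at -1.38 and PXDN at -1.52 prompted the hypothesis that let-7 target genes were lower as a set. The HMGA2 value rests on 1 of 2 compared probes, the other being at -0.08, and XPO4 was named here after its value was seen. Genes already seen, those past 2-fold included, were left out of its test. Of 40 other known let-7 targets 31 were compared, 27 were lower, and the median was -0.46 at percentile 0.03 of matched lists, with a range of 0 to 0.11 over 12 alternatives. After removal of the level trend 24 of the 31 were lower, and after scaling to the 75th percentile 22. DICER1 and THBS1 stood at -0.94, PBX2 at -0.96 and HMGA1 at -0.90, while the known targets IGF2BP1, IGF2BP2, IGF2BP3 and ARID3B stood at -0.18, -0.04, 0.03 and -0.10, and HIC2 was higher at 0.90.

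A control list of 51 targets of other microRNAs was written after the let-7 result and before its own. Of its members 42 were compared, 37 were lower, and the median was -0.33 at percentile 1.75, with a range of 0.08 to 3.82. After removal of the level trend 27 of the 42 were lower and after scaling to the 75th percentile 25, and the list lay inside the central 95% with the filter at the 60th percentile, at 3.82, and among genes whose probes have one sign, at 3.30. Examples were WEE1 at -0.88, TET3 at -0.86 and CCND1 at -0.84. The prediction that microRNA targets in general were lower was thus met in the values as deposited, though not under those 2 alternatives, so let-7 cannot be singled out, and the difference between the lists was not tested. A shared property of regulated transcripts may underlie both, and sites in the transcripts were not analysed here. Members of the control list may thus be let-7 targets as well, which limits it as a control. With 33 fixed lists, 152 families and these 2 lists examined, some would lie outside the central 95% by chance.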
